A study of Mus musculus with 14 samples.

How the data were processed

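Liver total RNA from 14 mice was labelled from 250 ng with the Affymetrix WT Plus protocol and hybridised to 1 array per mouse, per the labels' protocols. The authors deposited log2 values per probe set, made with RMA in Affymetrix Expression Console per the submitters' processing notes. RMA corrects background, equalises the distributions of the arrays and summarises the probes of each probe set, so a global difference in RNA content between groups would not be seen. The version, the library files and the genome build are not given in the sources used here. The treatment protocol gives a canagliflozin dose of 25 to 30 mg/kg and the sample labels give 30 mg/kg.

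Groups and replicate numbers were taken from the labels: HFD control (n = 4), HFD with canagliflozin (n = 5) and HFD with caloric restriction (n = 5). Each array was treated as 1 mouse; the labels count mice per group and do not state this array by array. Arrays have no depth, and their number limits the precision.

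Of 41345 probe sets, 23521 had 1 gene symbol in the platform annotation, 1814 had several and 16010 had no entry and are unnamed here. Probe sets with several symbols named no gene. Gene identifiers were matched to a RefSeq gene table, where 23328 matched and 0 had a different symbol. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, giving 22180 genes, all of which were tested without a filter on dim values. Some genes of the naming rule are not reported here.

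Group means were fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all groups share an estimate of the spread. Canagliflozin was compared with HFD control, caloric restriction with HFD control, and canagliflozin with caloric restriction. P values were adjusted by the Benjamini-Hochberg method per comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors from that fit, and group errors are standard deviations.

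Before the data were examined, 33 gene lists, the comparisons, the alternative settings and the naming rule were fixed. The lists cover mitochondrial fatty acid oxidation, peroxisomal and omega oxidation, other PPARα targets, ketogenesis, gluconeogenesis, glycolysis and glucose use, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, bile acids, lipid droplets, xenobiotic metabolism, male-biased and female-biased liver genes, amino acid catabolism and the urea cycle, the integrated stress response, endoplasmic reticulum chaperones and the unfolded protein response, oxidative phosphorylation, glucocorticoid-responsive genes, the circadian clock, the acute phase response, interferon-stimulated genes and the cell cycle. Marker lists cover macrophages, stellate cells, endothelial cells, cholangiocytes, lymphocytes, neutrophils, adipocytes, pancreatic acinar cells, erythroid cells, and pericentral and periportal hepatocytes. The erythroid list had 2 measured members, under the minimum of 3, and was not tested. The other 32 were tested with limma's camera with its preset correlation of 0.01 between genes, adjusted over the lists. Alternatives were camera with an estimated correlation, rank-based camera, fry and, chosen after the data were seen, an exact permutation of the mean value of a list's members per array.

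Genes were named by rule. In each direction these were up to 8 genes past the threshold with the most extreme log2 fold change, or the 5 with the smallest p where none passed, leaving out unnamed gene models, small RNAs and receptor families. Up to 4 members with the smallest p were named from each called list, and Slc5a1, Slc5a2, Fgf21, Pck1, G6pc, Ppargc1a, Cpt1a, Fasn, Scd1, Srebf1, Cyp7a1 and Igfbp1 in every comparison. This gave 113 genes. Genes named outside the rule are said to be chosen after their values were seen.

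The fit was tested on 10 simulated data sets of 22180 genes with 200 changed genes. Noise was drawn independently for each gene and array at the spread of the fit. The shares below therefore do not cover genes that vary together or an array that lies apart from its group. For canagliflozin against HFD control, 98.8% of genes changed 2-fold and 67.4% of those changed 1.5-fold were called, with 8.9 unchanged genes called per simulation. For canagliflozin against caloric restriction the shares were 99.2% and 77.2%, with 10.1 unchanged genes called. Among genes of the fixed lists, 89.2% and 91.4% of 2-fold changes and 54.3% and 60.2% of 1.5-fold changes were called in these comparisons.

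Other settings were a fit of only the 2 groups compared, filters at a mean log2 value of 5 or 6, median centring, cyclic loess, a trended and robust variance, array weights, the replicate number as a block, the mean of a gene's probe sets, all probe sets, other thresholds and leaving out each array. The position of an array in the deposited order was added as a linear covariate after the data were seen. Shared controls were addressed with 1000 simulations of unchanged groups and with 6 splits of the controls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.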

Results

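Hepatic RNA from male C57Bl/6J mice was measured on Affymetrix whole-transcript arrays. The mice received a 60% high-fat diet (HFD) from 6 weeks of age for 4 weeks to induce obesity, and were then studied for a further 4 weeks in 3 arms. The HFD control arm stayed on the diet (n = 4 arrays). The canagliflozin arm received the drug at 30 mg/kg with the diet (n = 5), and the caloric restriction arm ate 15 to 30% less so that body weight matched the drug arm (n = 5). Canagliflozin inhibits SGLT2, the glucose transporter that reclaims filtered glucose in the kidney. The comparisons ask which hepatic transcripts differ under the drug, which differ under weight-matched restriction without it, and which separate the drug from weight matching.

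All 14 arrays were alike in scale, with medians between 4.07 and 4.13 on the log2 scale and correlations between 0.968 and 0.988 for any pair. The number of arrays per group limits the precision. The median 95% confidence interval of a log2 fold change reached 0.25 to either side against the controls and 0.24 between the treated groups. Canagliflozin replicate 3 had the highest mean correlation of all 14 arrays with the arrays of other groups (0.984, against 0.978 with its own group), and its values are given where they set it apart. The first principal component held 20.3% of the variance, was negative in 7 of 14 arrays with both signs in every group, and varied with the position of the arrays in the deposited order. Over the 14 arrays r was 0.679 (permutation p = 0.00873, adjusted p = 0.0175 over 2 components), rho was 0.662 (permutation p = 0.0124) and r was 0.613 without the first and last array. The groups alternate in that order, and how it relates to the order of processing is not given in the sources used here. Slc5a2, which encodes the drug's target SGLT2, and Slc5a1, which encodes the related transporter SGLT1, had dim values in every group, and signal over background was not analysed here. Slc5a2 measured 4.30 ± 0.12 in HFD controls (SD, n = 4), 4.22 ± 0.18 under canagliflozin (n = 5) and 4.35 ± 0.21 under caloric restriction (n = 5). Slc5a1 measured 3.11 ± 0.13, 2.96 ± 0.44 and 2.87 ± 0.27 in the same order. Slc5a2 thus lay near the array medians and Slc5a1 near the lower quartiles of the arrays (2.99 to 3.06). These values do not show that either gene is expressed in liver.

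Against HFD controls, 17 of 22 genes of fatty acid and triglyceride synthesis had lower means under canagliflozin, while all 19 of mitochondrial and 14 of 16 of peroxisomal and omega oxidation had higher ones. Gluconeogenesis (9 of 15 genes higher) and amino acid catabolism (18 of 26 higher) were more mixed, and none of these 5 lists passed with an estimated correlation between genes (adjusted p from 0.494 to 0.564). Fasn, the fatty acid synthase, averaged 9.07 ± 0.72 (SD, n = 5) under the drug and 10.20 ± 0.36 (n = 4) in controls, which is 2.19-fold lower. Cyp4a14, a fatty acid omega-hydroxylase induced through PPARα, was 8.72-fold higher (10.47 ± 1.15 against 7.34 ± 1.60, and 5.57-fold without HFD control replicate 1), and Igfbp1, a secreted binding protein repressed by insulin, was 4.24-fold higher (10.73 ± 1.39 against 8.64 ± 0.27). No single gene passed the threshold over all 22180 genes in limma, where 1444 had an unadjusted p under 0.05 (711 higher and 733 lower) and 1109 would by chance. The gene groups below are therefore described by tests on lists fixed before the data were examined, and single members are given as values.

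The fatty acid and triglyceride synthesis list shifted down, with a mean log2 fold change of -0.29 over 22 measured genes (camera adjusted p = 3.6e-05 with the preset correlation, adjusted p = 0.494 with an estimated correlation). Of these genes 17 were lower and 5 higher in value, and 5 passed when adjusted over the list alone, against 0 over all genes. Scd1, the stearoyl-CoA desaturase, differed by -1.04 ± 0.33 (SE) on the log2 scale, and Acaca, which makes malonyl-CoA, by -0.42 ± 0.14. Mid1ip1, an activator of acetyl-CoA carboxylase, differed by -0.70 ± 0.22, although its 2 dimmer probe sets had values of the opposite sign. Srebf1, which encodes the lipogenic transcription factor SREBP-1, differed by -0.62 ± 0.24. The score of this list lay below every control array in 4 of 5 drug-treated mice, and canagliflozin replicate 3 was the exception. The cholesterol synthesis and uptake list was also called down (mean -0.28, 15 of 19 genes lower, camera adjusted p = 0.00247, adjusted p = 0.634 with an estimated correlation). Its members Stard4, a carrier of cholesterol, and Fdps, which makes farnesyl diphosphate, differed by -0.47 ± 0.16 and -0.71 ± 0.39. The mean of this list was -0.11 without HFD control replicate 3, -0.18 without HFD control replicate 4 or canagliflozin replicate 2, -0.50 without HFD control replicate 1 and -0.42 without canagliflozin replicate 5.

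Oxidative lists shifted up. All 19 measured genes of mitochondrial fatty acid oxidation had higher means under the drug, by 0.16 on average (camera adjusted p = 0.00027, adjusted p = 0.494 with an estimated correlation), although 0 passed when adjusted over the list alone. Acot2, a mitochondrial acyl-CoA thioesterase, differed by 0.88 ± 0.35, Hadhb of the trifunctional protein by 0.31 ± 0.12, from a dim probe set with a mean of 4.13, and Acadm, the medium-chain acyl-CoA dehydrogenase, by 0.26 ± 0.11. Cpt1a, which admits fatty acids to mitochondria, differed by 0.21 ± 0.14. Peroxisomal and omega oxidation shifted by 0.45 (camera adjusted p = 3.6e-05, adjusted p = 0.494 with an estimated correlation), with 14 of 16 genes higher and 2 passing when adjusted over the list alone, Cyp4a14 and Cyp4a31. Cyp4a31 was 3.78-fold higher, but near-identical Cyp4a copies share sequence and the value is uncertain. Ehhadh, the peroxisomal bifunctional enzyme, differed by 0.32 ± 0.12. The list of other PPARα target genes shifted by 0.37 (14 of 18 genes higher, camera adjusted p = 1.52e-05, adjusted p = 0.494 with an estimated correlation), and 3 of its genes passed when adjusted over the list alone. These were Acot1, a cytosolic acyl-CoA thioesterase (0.95 ± 0.25), Retsat, the retinol saturase (0.42 ± 0.14), and Slc22a5, the carnitine transporter (0.66 ± 0.22, with replicate 3 below the other drug-treated mice). Fgf21, a hepatic hormone induced by fasting, differed by 0.90 ± 0.32. Oxidative phosphorylation was called up with a mean of 0.10 over 29 genes (camera adjusted p = 0.0271, adjusted p = 0.634 with an estimated correlation), which was 0.063 without HFD control replicate 3.

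Gluconeogenesis was called up (mean 0.19, camera adjusted p = 0.017, adjusted p = 0.564 with an estimated correlation, and 0.311 with rank-based camera), although its median was 0.01 and 9 of 15 genes were higher. The 4 members that passed when adjusted over the list alone were Ppargc1a, a coactivator of the fasting response (1.14 ± 0.29), Got1, the cytosolic aspartate aminotransferase (0.89 ± 0.23), G6pc, which releases free glucose (0.56 ± 0.15), and Pck1, the cytosolic PEP carboxykinase (0.36 ± 0.10). Each of these 4 genes was above all 4 controls in 5 of 5 drug-treated mice. Amino acid catabolism and the urea cycle shifted by 0.16 over 26 genes, of which 18 were higher and 6 passed when adjusted over the list alone (camera adjusted p = 3.6e-05, adjusted p = 0.494 with an estimated correlation). Among them Ass1, the argininosuccinate synthase, differed by 0.48 ± 0.15, Tat, the tyrosine aminotransferase, by 0.40 ± 0.13, and Cth, which makes cysteine, by 0.38 ± 0.12. The glucocorticoid-responsive list had a mean of 0.29 with 13 of 17 genes higher (camera adjusted p = 0.00194, adjusted p = 0.6 with an estimated correlation), including the mTORC1 inhibitor Ddit4 (0.91 ± 0.29), and its mean was 0.17 without canagliflozin replicate 4. The lipid droplet list had a mean of 0.23 with 16 of 19 genes higher (camera adjusted p = 0.00326, adjusted p = 0.6 with an estimated correlation). Its members included Fabp4, a fatty acid carrier (0.56 ± 0.20), and the triglyceride lipase Pnpla2 (0.47 ± 0.21), for which replicate 3 again lay below the rest. Endoplasmic reticulum chaperones and the unfolded protein response shifted by -0.24, with 17 of 19 genes lower (camera adjusted p = 1.52e-05, adjusted p = 0.494 with an estimated correlation). Xbp1, the transcription factor of that response, differed by -0.44 ± 0.14, Pdia3, a disulfide isomerase, by -0.39 ± 0.14 and Sdf2l1, a chaperone partner, by -0.64 ± 0.25, each below all controls in 5 of 5 mice. Creld2, another secretory pathway gene, differed by -0.73 ± 0.24.

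The smallest p among higher genes belonged to Carmil1, a regulator of actin filament ends, at 6.97 ± 0.09 (SD, n = 5) against 6.34 ± 0.14 (n = 4) in controls (limma adjusted p = 0.133). Among lower genes it belonged to Rtkn at 4.88 ± 0.10 against 5.40 ± 0.11 (limma adjusted p = 0.181). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.42 ± 0.30. Without canagliflozin replicate 3, 12 genes passed the threshold in limma, 9 higher and 3 lower. They included Fasn (-1.41, adjusted p = 0.0122), Igfbp1 (2.59, adjusted p = 0.0486) and, chosen after its values were seen, the leptin receptor gene Lepr (2.45, adjusted p = 0.00214), each of which had an adjusted p of 0.559 with all arrays. Leaving out an array that lies apart narrows the spread of its group, which favours such calls. Of the 11 lists called, 8 up and 3 down, 0 kept an adjusted p under 0.05 with an estimated correlation, and the same held in the other comparisons. Leaving out 1 array ended 5 of these calls. Gluconeogenesis ended without HFD control replicate 1 or 2 or canagliflozin replicate 2 or 4 (highest adjusted p = 0.157). Cholesterol synthesis and oxidative phosphorylation ended without HFD control replicate 3 or 4 or canagliflozin replicate 1 or 2 (highest 0.352 and 0.386). Lipid droplet and glucocorticoid-responsive genes ended without HFD control replicate 1 or canagliflozin replicate 4 (0.0771 and 0.0751).

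**Figure D1:**
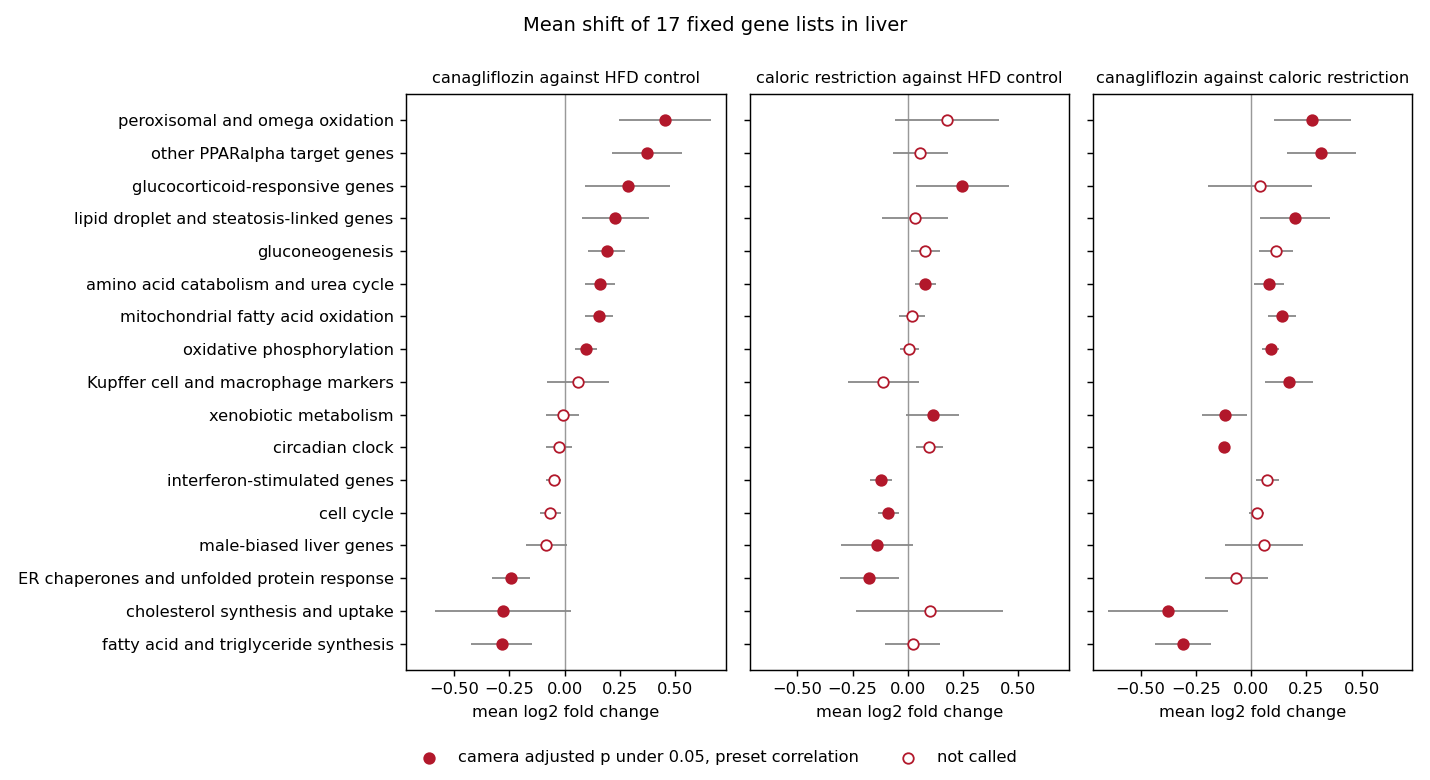
Mean log2 fold change of the 17 gene lists called in at least 1 comparison, with 1 panel per comparison and bars of ± 1 SE of the difference between group mean scores. Filled points were called by camera with the preset correlation and open points were not; fatty acid and triglyceride synthesis lies at -0.29 and -0.31 in the panels for canagliflozin and at 0.02 for caloric restriction against HFD control.

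Under caloric restriction to a matched weight, differences from HFD controls were small for Fasn, Scd1 and Cpt1a and larger for the omega-oxidation genes Cyp4a14 and Cyp4a31, of which the former depended on single arrays. Fasn averaged 9.93 ± 0.21 (SD, n = 5) against 10.20 ± 0.36 (n = 4), a difference of -0.27 ± 0.27 (SE), and Scd1 differed by -0.05 ± 0.33. Fgf21 differed by 0.20 ± 0.32, Ppargc1a by 0.28 ± 0.29, Cpt1a by -0.04 ± 0.14, Pck1 by 0.12 ± 0.10 and G6pc by 0.22 ± 0.15. Cyp4a14 averaged 8.62 ± 1.93 (SD, n = 5) against 7.34 ± 1.60 (n = 4), a difference of 1.27 ± 0.85 (SE) that was 0.63 without HFD control replicate 1, 0.66 without caloric restriction replicate 5 and 1.96 without caloric restriction replicate 3. Cyp4a31 differed by 0.92 ± 0.32 and Acot2 by 0.48 ± 0.35. The peroxisomal and omega oxidation list had a mean of 0.18 with 11 of 16 genes higher (camera adjusted p = 0.371), and mitochondrial fatty acid oxidation a mean of 0.02 with 9 of 19 higher (camera adjusted p = 0.993). The peroxisomal list was called up without caloric restriction replicate 3 (mean 0.29, adjusted p = 0.0159) or HFD control replicate 3 (0.33, adjusted p = 0.00689). Cholesterol synthesis and uptake had a mean of 0.10 with 16 of 19 genes higher (camera adjusted p = 0.448). It was called up without caloric restriction replicate 1 (0.23, adjusted p = 0.0391) or 3 (0.22, adjusted p = 0.00944) or HFD control replicate 3 (0.26, adjusted p = 0.00689). Igfbp1 differed by 0.74 ± 0.55 with 2 of 5 restricted mice above all controls. No gene passed the threshold in limma, the smallest adjusted p being 0.358, and 872 genes had an unadjusted p under 0.05 where 1109 would by chance. The intervals still allow sizeable effects, such as a log2 fold change of Fasn between -0.84 and 0.30.

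Of the fixed lists 7 were called in this comparison, 3 up and 4 down. Endoplasmic reticulum chaperones and the unfolded protein response shifted by -0.17, with 15 of 19 genes lower (camera adjusted p = 0.00262, adjusted p = 0.882 with an estimated correlation), including Pdia3 (-0.34 ± 0.14), Creld2 (-0.54 ± 0.24) and the calcium-binding chaperone Calr (-0.29 ± 0.14). Interferon-stimulated genes shifted by -0.12, with 15 of 18 lower (camera adjusted p = 0.00264, adjusted p = 0.472 with an estimated correlation), among them Irf7, a transcription factor of the interferon response (-0.22 ± 0.11), Isg15, a ubiquitin-like protein (-0.26 ± 0.14), and Oasl1 (-0.22 ± 0.11). Cell cycle genes shifted by -0.09, with 17 of 23 lower (camera adjusted p = 0.0184, adjusted p = 0.882 with an estimated correlation). The replicative helicase gene Mcm6 (-0.46 ± 0.12) was the 1 member that passed when adjusted over the list alone, and Ccnd1, which encodes cyclin D1, differed by -0.65 ± 0.24. Male-biased liver genes shifted by -0.14, with 16 of 19 lower (camera adjusted p = 0.00264, adjusted p = 0.882 with an estimated correlation). In that list the major urinary protein gene Mup21 differed by -0.31 ± 0.15, while Elovl3, a fatty acid elongase, differed the other way by 0.81 ± 0.30. Without caloric restriction replicate 5 the chaperone mean was -0.079 (camera adjusted p = 0.334) and the male-biased mean -0.015 (0.445), and the latter was -0.086 without caloric restriction replicate 1 and -0.22 without replicate 3. The cell cycle mean was -0.051 without HFD control replicate 2, and this call ended when only genes with a mean log2 of at least 5 or 6 were tested (adjusted p = 0.341 and 0.136).

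Glucocorticoid-responsive genes shifted up by 0.25, with 14 of 17 higher (camera adjusted p = 0.00262, adjusted p = 0.882 with an estimated correlation), including Ddit4 (0.82 ± 0.29), the clock gene Per1 (0.37 ± 0.17) and the cell cycle inhibitor Cdkn1a (0.92 ± 0.50). Xenobiotic metabolism shifted by 0.11, with 17 of 21 higher (camera adjusted p = 0.0217, adjusted p = 0.882 with an estimated correlation), and held the cytochrome P450 Cyp2c54 (0.37 ± 0.16) and the carboxylesterase Ces2a (0.21 ± 0.11). Amino acid catabolism and the urea cycle shifted by 0.08, with 22 of 26 higher (camera adjusted p = 0.0438, adjusted p = 0.997 with an estimated correlation), Got1 differing by 0.43 ± 0.23. The glucocorticoid mean was 0.092 without caloric restriction replicate 5 (camera adjusted p = 0.38) and 0.16 without HFD control replicate 1. The xenobiotic mean was 0.066 and 0.17 without HFD control replicate 1 or 4, and 0.071, 0.19 and 0.053 without caloric restriction replicate 1, 3 or 5. With the deposited order as a covariate, the xenobiotic and amino acid calls ended (adjusted p = 0.0514 and 0.0586). Genes with small p included E2f1, a transcription factor of the G1 to S transition (-0.41 ± 0.10), Rprd1a, a binder of RNA polymerase II (-0.37 ± 0.09), and Bcl2a1a of the BCL2 family (0.39 ± 0.10). The number of lists called fell to 2 without caloric restriction replicate 1, to 2 without caloric restriction replicate 5 and to 4 without HFD control replicate 1. Each of the 7 calls ended without at least 1 array, the interferon list only without caloric restriction replicate 1 (camera adjusted p = 0.0617), and chaperones and male-biased genes without caloric restriction replicate 1 or 5 (highest 0.334 and 0.445). Glucocorticoid-responsive genes ended without caloric restriction replicate 5 or HFD control replicate 1 (highest 0.38). Xenobiotic metabolism ended without caloric restriction replicate 1 or 5 or HFD control replicate 1 or 3 (highest 0.508). Amino acid catabolism ended without caloric restriction replicate 1, 2, 4 or 5 or HFD control replicate 1 or 2 (highest 0.508). The cell cycle call ended without caloric restriction replicate 1, 2 or 4 or HFD control replicate 2 (highest 0.475).

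Set directly against caloric restriction at matched weight, 19 of 22 genes of fatty acid and triglyceride synthesis and all 19 of cholesterol synthesis and uptake had lower means under canagliflozin, and 16 of 18 other PPARα target genes had higher ones. None of these 3 lists passed with an estimated correlation (adjusted p from 0.468 to 0.604). Fasn was 1.82-fold lower under the drug (9.07 ± 0.72 against 9.93 ± 0.21, SD, n = 5 and 5), Scd1 1.99-fold lower, and Thrsp, a lipogenic regulator, 1.76-fold lower. Acot1 was 1.75-fold higher, Ppargc1a 1.82-fold, Igfbp1 2.55-fold and Fgf21 1.62-fold higher. None of these 7 genes passed over all genes. The only gene that did was Rtkn, which was lower under the drug (4.88 ± 0.10 against 5.50 ± 0.12, log2 fold change -0.63 ± 0.087 (SE), limma adjusted p = 0.0264) and lay below all restricted mice in 5 of 5 drug-treated mice.

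**Figure D2:**
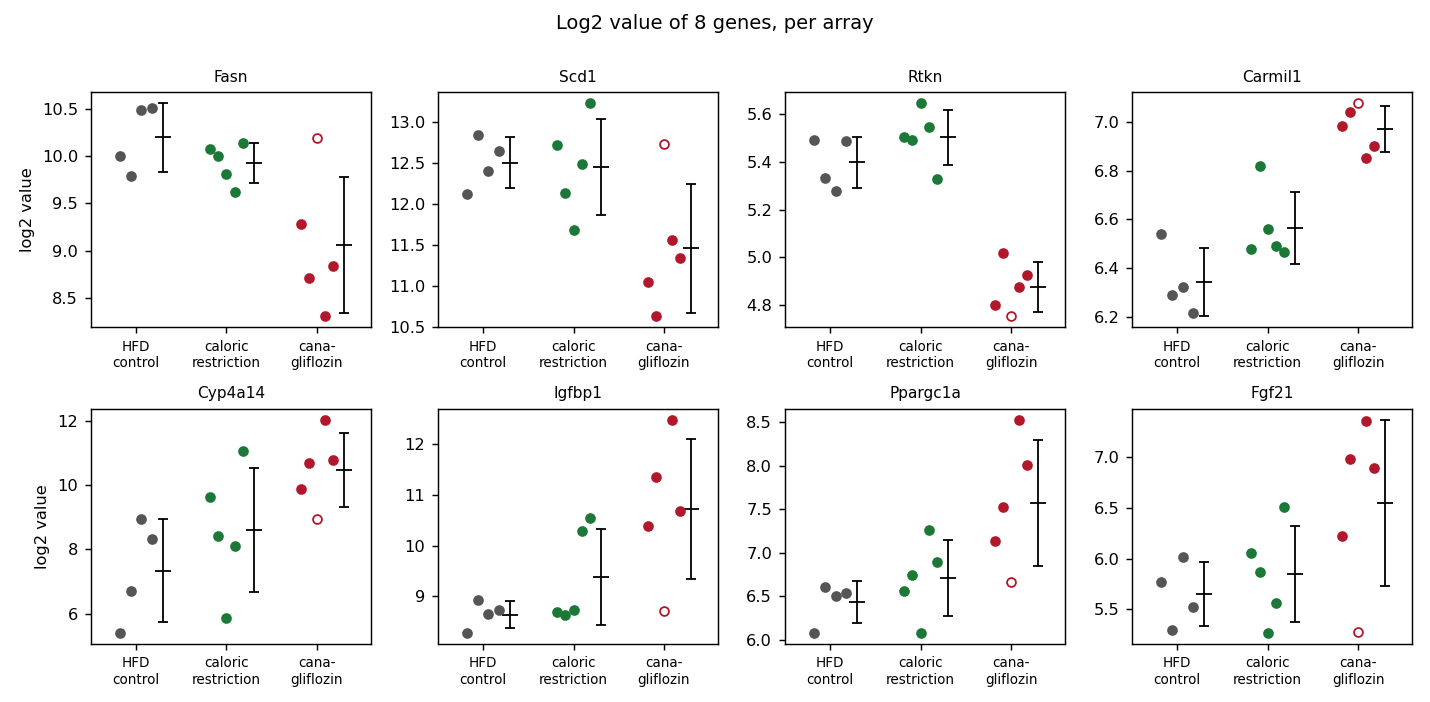
Log2 value of 8 genes in each array (1 point per array, HFD control n = 4, other groups n = 5) with the group mean and SD beside the points; the open point is canagliflozin replicate 3. For Rtkn and Carmil1 all 5 canagliflozin arrays lie apart from the HFD controls, and for Fasn, Igfbp1 and Fgf21 replicate 3 lies among the other groups.

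The fatty acid and triglyceride synthesis list shifted by -0.31 in this comparison (19 of 22 genes lower, camera adjusted p = 2.16e-06, adjusted p = 0.468 with an estimated correlation), and Thrsp, Fasn and Scd1 were the 3 genes that passed when adjusted over the list alone. Acss2, which makes acetyl-CoA from acetate, differed by -0.68 ± 0.25 (SE). Cholesterol synthesis and uptake shifted by -0.38, with all 19 genes lower (camera adjusted p = 1.18e-05, adjusted p = 0.604 with an estimated correlation), including Lss, the lanosterol synthase (-0.87 ± 0.36), and Fdps (-0.83 ± 0.37). The estimated correlation between genes of this list was 0.737, so that they varied as a block from mouse to mouse. The circadian clock list shifted by -0.12, with 15 of 18 genes lower (camera adjusted p = 0.0122, adjusted p = 0.45 with an estimated correlation). Against HFD control this list had a mean of -0.02 under the drug (7 of 18 genes higher, camera adjusted p = 0.319) and of 0.10 under restriction (12 of 18 higher, camera adjusted p = 0.371). The former was called down without HFD control replicate 2 (-0.074, adjusted p = 0.0437). Its mean score was 7.13 ± 0.03 (SD, n = 5) under the drug and 7.25 ± 0.04 (n = 5) under restriction, with no overlap between the groups (two-sided exact permutation p = 0.00794, the smallest this design allows, adjusted p = 0.254 over 32 lists). Bhlhe40, a clock repressor, differed by -0.40 ± 0.16 (SE), Tef by -0.27 ± 0.11 and Per3 by -0.26 ± 0.12. Xenobiotic metabolism shifted by -0.12 (16 of 21 genes lower, camera adjusted p = 0.0168, adjusted p = 0.604 with an estimated correlation), with Ces2a at -0.32 ± 0.11 and the cytochrome P450 Cyp2c55 at -0.67 ± 0.20, whose dimmer probe set had the opposite sign. The xenobiotic mean was -0.079, -0.20 and -0.061 without caloric restriction replicate 1, 3 or 5, and -0.0083 for the drug against HFD control (camera adjusted p = 0.936). This call also ended at a mean log2 of at least 6 (adjusted p = 0.0737), with the mean of a gene's probe sets (0.0605) and with the deposited order as a covariate (0.0813).

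Other PPARα target genes shifted up by 0.32 (16 of 18 higher, camera adjusted p = 1.18e-05, adjusted p = 0.468 with an estimated correlation), including Retsat (0.35 ± 0.13) and the lipid droplet coat gene Plin2 (0.29 ± 0.12). Mitochondrial fatty acid oxidation shifted by 0.14 (15 of 19 higher, camera adjusted p = 0.000137, adjusted p = 0.487 with an estimated correlation). Its members included Hadhb at 0.36 ± 0.12, from the dim probe set named above, and Etfa, an electron carrier of the pathway, at 0.26 ± 0.11. Peroxisomal and omega oxidation shifted by 0.28 (14 of 16 higher, camera adjusted p = 0.00134, adjusted p = 0.602 with an estimated correlation), including Crot, the carnitine octanoyltransferase (0.27 ± 0.11). Lipid droplet genes shifted by 0.20 (15 of 19 higher, camera adjusted p = 0.00577, adjusted p = 0.604 with an estimated correlation), among them the lipolysis inhibitor G0s2 (0.82 ± 0.30, replicate 3 below the other drug-treated mice). Oxidative phosphorylation shifted by 0.09 (24 of 29 higher, camera adjusted p = 0.0122, adjusted p = 0.62 with an estimated correlation). Amino acid catabolism and the urea cycle shifted by 0.08 (19 of 26 higher, camera adjusted p = 0.0188, adjusted p = 0.66 with an estimated correlation), with the homogentisate dioxygenase gene Hgd at 0.24 ± 0.08, Oat, the ornithine aminotransferase, at 0.31 ± 0.12 and Nags, which makes the activator of the urea cycle, at -0.32 ± 0.12. Kupffer cell and macrophage markers shifted by 0.17 (17 of 20 higher, camera adjusted p = 0.00223, adjusted p = 0.602 with an estimated correlation), with the perforin-like gene Mpeg1 at 0.40 ± 0.17 and the scavenger receptor gene Marco at 0.61 ± 0.39. The endothelial marker list had a mean of -0.08 in the same comparison and was not called (camera adjusted p = 0.184). It was called down without canagliflozin replicate 3 (-0.11, adjusted p = 0.0388) or 4 (-0.12, adjusted p = 0.0185) or caloric restriction replicate 3 (-0.13, adjusted p = 0.0127). Without 1 array, means moved to 0.17 for peroxisomal oxidation and 0.049 for amino acid catabolism (caloric restriction replicate 3), to 0.030 for amino acid catabolism and 0.058 for oxidative phosphorylation (canagliflozin replicate 2), and to 0.089 for macrophage markers (caloric restriction replicate 5). The macrophage call also ended at a mean log2 of at least 6 (adjusted p = 0.0575), and oxidative phosphorylation with the deposited order as a covariate (0.0568).

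In limma 1341 genes had an unadjusted p under 0.05, 680 higher and 661 lower, and the next smallest p after Rtkn belonged to Ppp1r3c, a glycogen-targeting subunit of protein phosphatase 1, chosen after its values were seen (-1.81 ± 0.29, limma adjusted p = 0.105). Among higher genes with small p were Fh1, the fumarate hydratase (0.61 ± 0.13), Brap, a BRCA1-associated protein (0.49 ± 0.10), and Pawr, a regulator of apoptosis (0.48 ± 0.10). The Rtkn call held in 6 of the 14 fits that left out 1 array each, with adjusted p between 0.0193 and 0.138. It was lost without canagliflozin replicate 1, 4 or 5, caloric restriction replicate 1, 2, 3 or 4, or HFD control replicate 2, and also when only the 2 groups were fitted (adjusted p = 0.134). The Rtkn call was also lost with the replicate block and with all probe sets (smallest limma adjusted p = 0.117 for any probe set). Without canagliflozin replicate 3, 16 genes passed, 10 higher and 6 lower, and 8 of them also passed against HFD control in the same direction. Leaving out an array that lies apart narrows the spread of its group. Both comparisons use the same remaining canagliflozin arrays, so the 8 genes are not independent evidence. Among the lists, the circadian clock and macrophage calls ended without caloric restriction replicate 5 (adjusted p = 0.0514 and 0.131), peroxisomal oxidation without caloric restriction replicate 3 (0.0511), and lipid droplets without caloric restriction replicate 3 or 4 or canagliflozin replicate 4 (highest 0.0978). Xenobiotic metabolism ended without canagliflozin replicate 1 or caloric restriction replicate 1 or 5 (highest 0.235), amino acid catabolism without canagliflozin replicate 2 or caloric restriction replicate 3 (highest 0.527), and oxidative phosphorylation without canagliflozin replicate 2 or caloric restriction replicate 2 (highest 0.364). Other lists were called only without 1 array. Gluconeogenesis was called up without canagliflozin replicate 1 or 3 (adjusted p = 0.0417 and 0.0388, and 0.146 with all arrays). Interferon-stimulated genes were called up without canagliflozin replicate 1 or caloric restriction replicate 2 or 3 (lowest 0.0252, and 0.0983 with all arrays). Male-biased genes were called up without canagliflozin replicate 4 or caloric restriction replicate 2 or 3 (lowest 0.00748, and 0.213 with all arrays). Endoplasmic reticulum chaperones were called down without caloric restriction replicate 1 or 5 (0.0399 and 0.001, and 0.207 with all arrays).

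**Figure D3:**
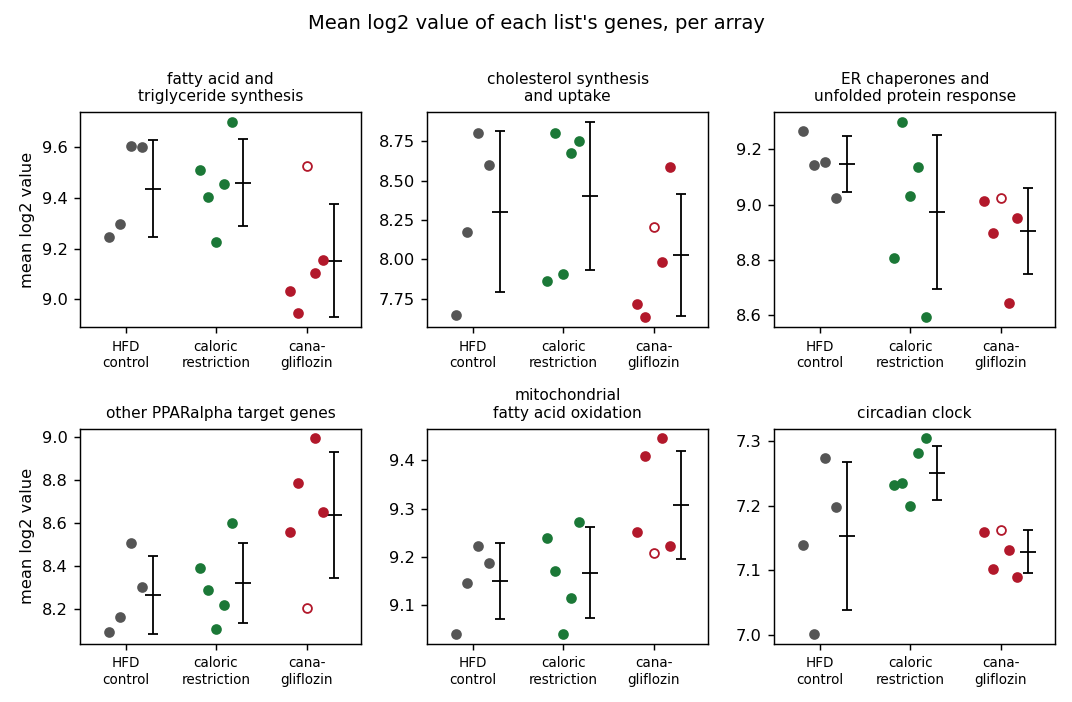
Mean log2 value of the genes of 6 lists in each array (1 point per array, HFD control n = 4, other groups n = 5) with the group mean and SD beside the points; the open point is canagliflozin replicate 3. The circadian clock scores of the 5 canagliflozin arrays lie below those of all 5 caloric restriction arrays, and 4 of 5 canagliflozin arrays lie below every HFD control array for fatty acid and triglyceride synthesis.

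The effects of the drug and of restriction, each against the same HFD controls, correlated across genes with r = 0.517 and a covariance of 0.0111. Of genes with an unadjusted p under 0.05 in both, 114 were higher and 125 lower in both, against 14.6 and 13.7 for independent lists. Genes are not independent replicates, and shared controls alone gave r = 0.541 ± 0.235 (SD) and a covariance of 0.0116 in simulated unchanged groups. With the controls split so that each effect had its own pair, r lay between -0.117 and 0.118 over 6 splits. No gene passed the threshold in the same direction against both HFD control and caloric restriction under canagliflozin. At an unadjusted p under 0.05 in both, 391 genes did, 223 higher and 168 lower, against a mean of 251 (SD 429) in simulated unchanged groups, 21 of 100 of which gave as many, and 43.6 for independent lists. The simulations drew arrays with replacement, so that the same array could enter a group again, and these counts ranged from 0 to 2341.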

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

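The tests of array quality, of a wrong label, of an exchange with caloric restriction replicate 5 and of cell makeup, and the counts of splits for genes past the threshold, were chosen only after the result was seen.

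In 23 of 390 groups of values, 1 array lay far from the rest of its group, where the nominal rate is 1 group in 20, or 19.5. The values were those of named genes and called lists, mostly picked by small p in these data, and they vary together. The 2 counts therefore do not measure an excess or its absence. Canagliflozin replicate 3 was the distant array 4 times, with G0s2 at 7.04 (mean of the other 4 arrays 8.39), Slc22a5 at 6.46 (7.61), Pnpla2 at 8.42 (9.59) and Oasl1 at 6.23. Canagliflozin replicate 4 was distant at Calr (10.39), Pdia3 (9.43) and Acot1 (7.72), and canagliflozin replicate 2 at Acadl (10.45), Ndufa9 (9.52) and Endou (3.65). Caloric restriction replicate 3 was distant at Ccnd1 (7.18) and Slc5a2 (3.99), replicate 5 at Gadd45g (8.97, mean of the others 7.37) and Cd14 (3.96), replicate 4 at Gemin2 (3.67) and replicate 2 at Carmil1 (6.82). HFD control replicate 3 was distant at Mvd (6.27), Acaa1a (7.96) and Gstm2 (6.58), replicate 1 at Per3 (6.82) and Sc5d (10.58), and replicate 4 at Cyp2c55 (6.27) and in the mean of male-biased liver genes (9.44, mean of the others 9.62).

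Canagliflozin replicate 3 lay at 0.0286 on a scale from the mean of the other groups (0) to that of the other drug-treated mice (1). Both means were taken without the array placed. The remaining drug-treated mice lay between 0.372 and 0.890. Arrays of the other groups lay between 0.0329 and 0.559, with HFD control replicate 2 at 0.380. The scale therefore did not part the groups, and canagliflozin replicate 3 lay below every other array. Low array quality is argued against by its mean correlation of 0.984 with the other groups, the highest of all arrays, which noise would lower, although its array weight (0.834) and its mean correlation with its own group (0.978) were the lowest. A wrong label stays open: at 176 genes chosen without it, it lay beyond all arrays of the other groups at 20, where chance gives 17.6, and caloric restriction replicate 5 had the highest position of the other groups (0.559). At 178 genes chosen without both arrays, canagliflozin replicate 3 lay beyond the rest at 24 and caloric restriction replicate 5 at 82, against 19.8 by chance. An exchange of the pair could account for the pattern at these genes. These chance values take genes as independent and the left-out arrays as like the others, although only the others were used to choose the genes. List scores went both ways. The PPARα target scores, 8.21 in canagliflozin replicate 3 and 8.60 in caloric restriction replicate 5, go with an exchange. Fatty acid synthesis in caloric restriction replicate 5 (9.70) was the highest of all arrays, against 8.94 to 9.15 in the other canagliflozin arrays. Its clock score (7.30) was also the highest, and canagliflozin replicate 3 (7.16) lay below all restricted mice. An exchange would leave these values unexplained. A weaker drug effect in the mouse of canagliflozin replicate 3, for which no drug level was used here, may also account for the position of that array. It would leave the position of caloric restriction replicate 5 unexplained.

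Macrophage markers were higher under canagliflozin than under caloric restriction, which a lower share of hepatocyte RNA could produce if other cell types moved alike. Against HFD control the list had a mean of 0.06 under canagliflozin (camera adjusted p = 0.319) and of -0.11 under restriction (15 of 20 genes lower, camera adjusted p = 0.119), beside -0.12 for interferon-stimulated and -0.09 for cell cycle genes under restriction. It was called without HFD control replicate 1 or 2 in the first of these comparisons (mean 0.13 in both), and without HFD control replicate 3 or 4 or caloric restriction replicate 2 or 4 in the other (-0.22, -0.14, -0.16 and -0.15). The macrophage minus endothelial score was 0.25 higher under the drug (SD 0.188 and 0.159, n = 5 and 5), with a two-sided exact permutation p = 0.0635, and the endothelial list itself was called down without canagliflozin replicate 3 or 4 or caloric restriction replicate 3 (-0.11, -0.12 and -0.13). This neither excludes nor establishes a change in cell makeup, and a change in macrophages themselves stays open as untested.

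How often other splits of the arrays give as much was examined with 100 of the possible splits per comparison, the real split included. With a real count of 0 genes past the threshold, all 100 splits give at least as many, so this count says nothing for either comparison against HFD control (highest other 38 for canagliflozin and 1 for caloric restriction). Chance could not be excluded for canagliflozin against HFD control, where 19 splits gave as many genes with an unadjusted p under 0.05 (1444, highest other 2065) and 9 as many lists (11, highest other 14). It could not be excluded for caloric restriction against HFD control, where the numbers were 66 splits for 872 genes (highest other 1847) and 43 for 7 lists (highest other 18). It could not be excluded for canagliflozin against caloric restriction, with 6 splits for 1 gene (highest other 19), 19 for 1341 genes (highest other 1657) and 18 for 11 lists (highest other 14). Splits that call many more genes than the real one point to a structure of the samples. The split with 38 genes parted 9 of 9 arrays by the sign of the first principal component, which varied with the deposited order (r = 0.679), while the splits with 1847 and 2065 genes parted 8 of 9 and 7 of 9 so. These splits were picked for their high counts and the component comes from the same arrays, so this agreement is not independent evidence. A split with 37 genes between canagliflozin and HFD control arrays put canagliflozin replicate 3 with all HFD controls against the other canagliflozin arrays. The split with 19 genes exchanged canagliflozin replicate 3 with caloric restriction replicate 5, with 8 of 10 arrays on the side of their sign. With the deposited order as a covariate, 1, 1 and 1 genes and 11, 5 and 9 lists passed in the 3 comparisons. For the 391 genes with an unadjusted p under 0.05 against both groups, 3 of 100 regroupings of all arrays, the real one included, gave as many (highest other 419). Of the simulations of unchanged groups 21 of 100 did (highest 2341). These could draw the same array into a group again, which can narrow its spread and raise the count. Whether chance can be excluded stays unsettled.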

How the results depend on the processing

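The exact score permutation and the deposited order as a covariate were chosen only after the data were seen, as were the names Olfr331 and Angptl8. Of 3844 values of named genes over all alternatives, 3835 kept their sign, 13 newly passed the threshold and 10, all of Rtkn, no longer did. Of 812 pairs of a called list and a setting, 662 stayed past the threshold, 150 did not and 0 changed sign. With an estimated correlation, with fry and with the score permutation, 0 lists were called in every comparison, against 11, 7 and 11 with the preset correlation; these tests allow for genes of a list varying together. The score permutation could call a list only if several reached its smallest p of 0.00794, which adjusts to 0.254 for 1 of 32. Rank-based camera called 11, 7 and 12. For canagliflozin against caloric restriction 0 genes passed when only the 2 groups were fitted, at a mean log2 of at least 6 (Rtkn is then not tested) and with all probe sets. For canagliflozin against HFD control 1 gene passed, Carmil1, at a mean log2 of at least 5 or 6, where fewer genes are tested. With the deposited order as a covariate, 1 gene, Olfr331, passed lower in each comparison against HFD control, Rtkn still passed, and 11, 5 and 9 lists were called; the cause was not tested. With the HFD controls split, the correlation of both effects was 0.0219 in place of 0.517. Replicate numbers were not taken as pairs in the main fit, as 7 of 13 same-number pairs, not all, correlated above 0.1. Of 14 arrays, 6 correlated best with their own number. Mean r was 0.102 for same-number pairs and -0.025 for other pairs, so that a partial pairing stays open. With the replicate block, 2 genes passed between canagliflozin and caloric restriction, Angptl8 and Ppp1r3c but not Rtkn. For caloric restriction against HFD control 4 lists were then called, without xenobiotic metabolism, male-biased and glucocorticoid-responsive genes. The means of these lists were 0.080, -0.080 and 0.14 with the block (camera adjusted p = 0.208, 0.0571 and 0.0540). The cause was not tested.

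Leaving out each array in turn, genes past the threshold ranged from 0 to 12 for canagliflozin against HFD control (12 without canagliflozin replicate 3, and 1 without replicate 5), from 0 to 0 for caloric restriction against HFD control and from 0 to 16 for canagliflozin against caloric restriction (16 without canagliflozin replicate 3, and 2 without replicate 2). Genes past both ranged from 0 to 8. Lists ranged from 8 to 12, from 2 to 10 and from 9 to 13, and the correlation from 0.453 to 0.614. Differences near 0 changed sign. For caloric restriction against HFD control, Cyp7a1 (0.20 with all arrays) ranged from -0.0469 (without HFD control replicate 1) to 0.36. Scd1 ranged from -0.24 to 0.14, with 0.06 and 0.03 without HFD control replicate 2 or caloric restriction replicate 2. Cpt1a ranged from -0.13 to 0.0193, with 0.0188 and 0.0011 without HFD control replicate 4 or 3. For canagliflozin against caloric restriction, Slc5a1 ranged from -0.0581 to 0.22, with -0.0118 without caloric restriction replicate 2. Signal over background was not analysed here.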

Other observations

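The choice of Lepr, Ppp1r3c, Ppp1r3g, Pklr, Abcb4, Elovl3, Ccnd1 and Mcm5 here, and 3 of the 4 relations between scores, came only after the result was seen. Outside the called lists, Pklr, the liver pyruvate kinase, was lower under canagliflozin than under caloric restriction by a log2 difference of -0.82 ± 0.19 (SE) and passed when adjusted over the list alone (adjusted p = 0.005 in limma), although its list of glycolysis and glucose use was not called. Abcb4, which exports phospholipid into bile, was higher by 0.39 ± 0.10 and passed when adjusted over its list alone. Against HFD control, Elovl3 was higher by 1.17 ± 0.30, and Ccnd1 differed by -0.89 ± 0.24 and Mcm5, another replicative helicase gene, by -0.32 ± 0.09, each passing when adjusted over its list alone. Between the drug and restriction, genes that passed without canagliflozin replicate 3 but not with all arrays included Ppp1r3c at -2.11 (limma adjusted p = 0.00123, and 0.105 with all arrays), Ppp1r3g at 1.39 (0.0426, and 1.04 with adjusted p = 0.683 with all arrays) and Lepr at 2.00 (0.00709, and 1.45 with adjusted p = 0.683).

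With all arrays and genes, the remaining lists were not called by camera in any comparison. At a mean log2 of at least 6, the integrated stress response was called up for canagliflozin and for restriction against HFD control (means 0.21 and 0.20, adjusted p = 0.0175 and 0.00912). Without caloric restriction replicate 3, female-biased genes were called up for restriction against HFD control (0.19, adjusted p = 0.022). Endothelial markers were called down between canagliflozin and restriction without canagliflozin replicate 3 or 4 or caloric restriction replicate 3 (-0.11, -0.12 and -0.13). In the order canagliflozin against HFD control, restriction against HFD control and canagliflozin against restriction, mean log2 fold changes were 0.08, 0.04 and 0.04 for ketogenesis, 0.12, 0.07 and 0.05 for glycolysis and glucose use, and 0.09, 0.08 and 0.01 for bile acids. They were 0.10, 0.11 and 0.00 for female-biased genes, 0.08, 0.06 and 0.02 for the integrated stress response, and -0.04, -0.05 and 0.01 for the acute phase response. Among marker lists they were 0.02, -0.04 and 0.05 for stellate cells, -0.02, 0.05 and -0.08 for endothelial cells, 0.10, 0.01 and 0.09 for cholangiocytes, 0.00, 0.00 and 0.01 for lymphocytes, and 0.07, 0.00 and 0.07 for neutrophils. They were 0.01, -0.01 and 0.02 for adipocytes, 0.03, 0.01 and 0.02 for pancreatic acinar cells, -0.01, 0.02 and -0.04 for pericentral and 0.07, 0.02 and 0.05 for periportal hepatocytes. Scores per array were dim for neutrophils (3.24 to 3.47), pancreatic acinar cells (3.39 to 3.66), lymphocytes (3.81 to 4.11) and cholangiocytes (3.88 to 4.15). Small means of these dim lists do not show that the cells were unchanged. For glycolysis the mean was positive while camera's direction was down in both comparisons with canagliflozin.

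A hypothesis was that the opposite shifts of lipid synthesis and PPARα target genes may follow differences in nutritional state between mice, so that both scores would run against each other within groups. Over the 14 arrays, deviations from the group means gave r = 0.0345 (permutation p = 0.918) and rho = 0.305 (permutation p = 0.324). The predicted negative r was not found, which by the outcome set beforehand goes against the hypothesis. With so few arrays a weak relation of either sign is not excluded. Without the 2 arrays farthest in lipid synthesis, canagliflozin replicate 3 and caloric restriction replicate 5, r was 0.477, and without canagliflozin replicate 3 alone it was 0.738, so that 1 array carries the value. Among the 5 canagliflozin arrays, too few for a coefficient, the sign was negative. Canagliflozin replicate 3 had both the highest lipid synthesis score (9.53) and the lowest PPARα target score (8.21) of these 5. That sign therefore rests on 1 array, for which a wrong label stays open, and does not speak for the hypothesis. Of 4 relations computed, fatty acid and cholesterol synthesis had r = 0.622 (permutation p = 0.0300, adjusted p = 0.120) and rho = 0.596 (permutation p = 0.0456), with r = 0.673 without those arrays and 0.704 without canagliflozin replicate 3. Fatty acid synthesis against glucocorticoid-responsive genes gave r = 0.340 (permutation p = 0.277, adjusted p = 0.427), rho = 0.424 (permutation p = 0.168) and r = 0.656 without those arrays, and 0.860 without canagliflozin replicate 3. Against endoplasmic reticulum chaperones it gave r = -0.296 (permutation p = 0.320, adjusted p = 0.427), rho = -0.262 (permutation p = 0.413) and r = -0.286 without those arrays, and -0.560 without canagliflozin replicate 3. Among the canagliflozin arrays alone the sign of both relations turned. There canagliflozin replicate 3 had the lowest glucocorticoid score (7.66) and the highest chaperone score (9.02), so that both turns rest on 1 array.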
